A study of Homo sapiens with 9 samples.

How the data were processed

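Total RNA from HEK293 cells, grown in DMEM with serum and transfected for 48 h with control, DBC1 or ZNF326 siRNA, was purified on columns with DNase treatment, depleted of ribosomal RNA and labelled for Affymetrix whole-transcript arrays, per the labels. The design lists 3 independent experiments per siRNA, 9 arrays in all. The deposited values are log2 expression values that the authors made with RMA (background correction, normalization across arrays and summary of probes), 1 value per probe set, here a transcript cluster, and array. The base of the logarithm rests on RMA and on the range of the values, 0.333 to 13.4. The version of the RMA software and the filters applied were not given in the sources used here, and the probe annotation refers to build hg18. No background or detection values, scanner files or exon-level values were used here, so alternative splicing was not analysed here and levels near background were not marked. The depth of an array is not a count, and the number of arrays limits the precision. In the table, 41.4% of probe sets had the same value on at least 2 arrays and 23.7% on at least 3.

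Of 22011 probe sets, 14432 carried 1 gene symbol, 2408 several and 5171 none. Symbols were checked against a current gene table through gene identifiers, which matched 14404 probe sets and changed 0 symbols. DBC1 was read as CCAR2, since BRINP1, another gene, once had the same symbol. Genomic spans came from a table on assembly GRCh38.p14 and served to rank genes by length, with a span for 14205 genes (99.8%). No coordinates are given because the builds differ.

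A linear model with the 3 groups was fitted to every probe set with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without filter or rescaling. Each of the 3 pairs of groups was compared with a two-sided moderated test, the p values were adjusted by Benjamini and Hochberg within the comparison, and an adjusted p below 0.05 was a call. Values are means over 3 arrays with SD, or differences with the standard error of the model, and fold changes are powers of 2 of the log2 change. A probe set was separated when all 3 arrays of one group lay on one side of all 3 of the other. Over all groupings chance gives this on average in 10% of cases without tied values and in fewer with them. Probe sets vary together, so a single grouping can lie above that average, and how far was not measured.

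Gene groups were 30 lists: integrated stress response, p53 targets, interferon and double-stranded RNA response, NF-kB targets, heat shock proteins, unfolded protein response of the endoplasmic reticulum, hypoxia targets, immediate early genes, apoptosis, S-phase genes, G2/M genes, replication-dependent histones, RNA polymerase II subunits, elongation factors, SR proteins, hnRNP genes, core spliceosome, siRNA machinery, partners of SIRT1 and CCAR2, ribosomal proteins, oxidative phosphorylation, glycolysis, cholesterol synthesis, circadian clock, TGF-beta targets, Wnt targets, and epithelial, fibroblast, neuronal and haematopoietic markers. Lists were tested on 1 probe set per symbol, the one with the highest mean, with camera at a preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Members were also counted with p values adjusted over the list alone. Medians were taken over the measured members. The 10% of genes with the longest span were tested against the other genes in the same way. This was planned for siDBC1 and siZNF326 against siCTR, and the length comparison between siZNF326 and siDBC1 was added to the plan. The lists, comparisons, tests, thresholds, alternatives and the rule for naming genes were chosen before the data were examined, apart from the choices named as made later.

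Genes were named from probe sets with 1 symbol by this rule: always CCAR2, ZNF326, BRINP1, CCAR1 and SIRT1. For siDBC1 and siZNF326 against siCTR they were the 12 largest rises and 12 largest falls among called genes whose arrays were separated, and 6 per direction between siZNF326 and siDBC1. Up to 8 shared calls per direction and up to 4 members with the smallest p per list were added. Other genes are said to be chosen after their values were seen.

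Calls shared by siDBC1 and siZNF326 were set beside the number that independent calls would share and beside 100 simulated sets of unchanged groups. Those sets drew all 9 arrays anew as random combinations of the residuals of the real ones, which keeps the correlation between genes, and set both unchanged groups against 1 drawn control group. The fit was tested on simulated data with 200 changed probe sets in each of 20 simulations. It called 22.8% of 1.5-fold, 48.4% of 2-fold and 81.7% of 4-fold changes in siDBC1 against siCTR, and 24.8%, 51.1% and 83.9% in siZNF326 against siCTR. Among the probe sets left unchanged in these simulations the median number of calls was 0 and the highest was 34 and 93. In the 100 simulated sets of unchanged groups the median number of calls was 0 and the highest 2439 in siDBC1 and 105 in siZNF326, with as many as observed in 2 and 1 sets. A planted shift of −0.5 in a list was found in 20 of 20 simulations, and with no shift camera passed a median of 3.5 and at most 18 of 30 lists.

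Alternatives were a replicate block, quantile normalization, centring of arrays on their medians, filters on dim probe sets, probe sets with 1 symbol, trend and robust eBayes, array weights, a fit of the 2 groups compared, a fold minimum of 1.5, an adjusted p below 0.01, leaving out each array, other list tests and other definitions of long genes. An axis through the arrays, the first singular vector of the residuals, was used as a covariate, and the 3 arrays farthest out on it were left out, both chosen after seeing the data. That omission left siDBC1 with replicate 1 alone, so its siDBC1 values rest on 1 array. Quantile normalization and centring moved the median change of all probe sets by less than 0.1 on the log2 scale. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.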

Results

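Gene expression was measured in HEK293, a human embryonic kidney cell line, 48 h after transfection with small interfering RNAs (siRNAs) labelled as control (siCTR), DBC1 (siDBC1) or ZNF326 (siZNF326). Each group held 3 arrays, 9 in all, and the table gave 1 log2 value for each of 22011 probe sets. DBC1 is the protein of the gene CCAR2, and ZNF326, also called ZIRD, is a zinc finger protein. Both are studied as subunits of a complex that links RNA polymerase II with messenger ribonucleoprotein particles, so the comparisons ask which transcripts change when either subunit is depleted and whether the same ones change. Array medians ran from 5.67 to 5.78 in siCTR, from 5.58 to 5.89 in siDBC1 and from 5.76 to 5.90 in the arrays labelled siZNF326, on the log2 scale. Correlations between arrays, taken across probe sets that are not independent replicates, ran from 0.953 to 0.988. The number of arrays limits the precision of every value.

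CCAR2, the transcript targeted by siDBC1, fell in that group. Its probe set (3089597) stood at 7.72 ± 0.096 in siCTR (SD, n = 3) and 6.56 ± 0.078 in siDBC1 on the log2 scale, a change of −1.16 (SE 0.079, adjusted p = 0.0116) or 2.24-fold, lower in all 3 arrays. ZNF326 was not lower in the arrays labelled siZNF326. It stood at 5.55 ± 0.27 in siCTR (SD, n = 3) and 5.83 ± 0.28 there, a difference of 0.28 (SE 0.39, adjusted p = 0.851) with a 95% interval from −0.63 to 1.20. In siDBC1 the ZNF326 arrays read 6.24, 5.64 and 7.32, a mean difference from siCTR of 0.85 (adjusted p = 0.844). The group name is therefore used below as a label of the arrays, since the depletion it names was not seen in the transcript. CCAR2 itself differed by 0.26 from siCTR in the arrays labelled siZNF326, higher in all 3 of them, and did not pass (adjusted p = 0.377). BRINP1, another gene that once carried the symbol DBC1, differed from siCTR by 0.049 in siDBC1 (adjusted p = 0.991) and by −0.061 in siZNF326 (adjusted p = 0.839). It read the same value, 3.66, on all 3 siCTR arrays, below the lower quartile of each, so the lack of a change says little. SIRT1, a deacetylase that the CCAR2 protein inhibits, differed by −0.055 (adjusted p = 0.999) and 0.22 (adjusted p = 0.811). CCAR1, the paralog of CCAR2, differed by 0.20 (adjusted p = 0.985) and 0.38 (adjusted p = 0.734). The fall of CCAR2 ranged from −1.21 to −1.11 when 1 array at a time was left out. Its adjusted p was 0.0843 without siCTR replicate 2, 0.122 without siDBC1 replicate 1, 0.0544 without siDBC1 replicate 2 and 0.0629 without siZNF326 replicate 3.

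**Figure D1:**
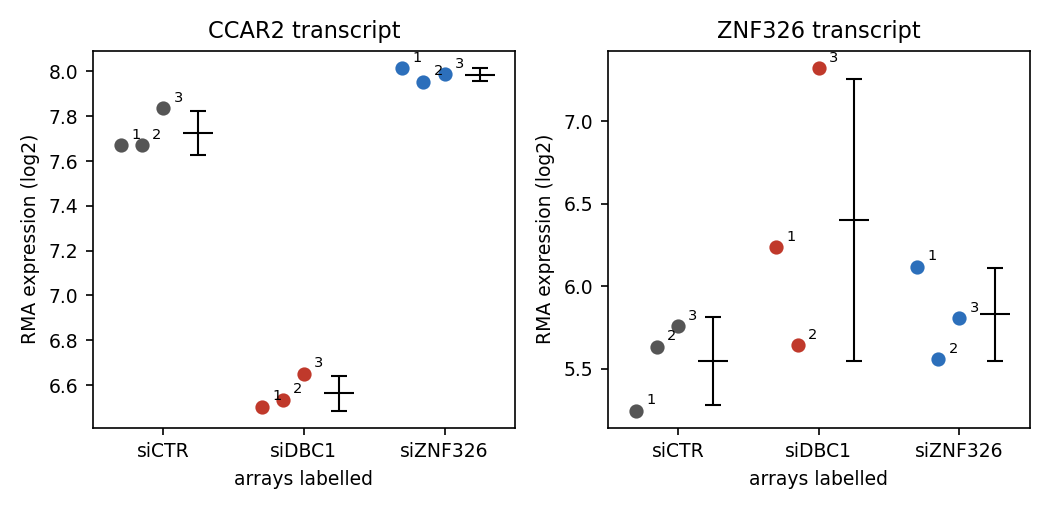
Log2 expression (y axis) of the siRNA targets on each of the 9 arrays, by group (x axis); numbered points are arrays and the bar at the right of each group is the mean ± SD of its 3 arrays. CCAR2 lies between 6.50 and 6.65 in siDBC1 and at or above 7.67 on the other 6 arrays, while ZNF326 lies between 5.56 and 6.12 in the arrays labelled siZNF326 and between 5.25 and 5.76 in siCTR.

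In siDBC1, transcripts of the integrated stress response fell beside CCAR2. CHAC1, which degrades glutathione and is a target of the stress factor ATF4, went from 7.75 ± 0.17 (SD, n = 3) to 6.29 ± 0.030, a change of −1.46 (SE 0.11, adjusted p = 0.0116) or 2.75-fold. ASNS, asparagine synthetase, fell by 1.04 (SE 0.11, adjusted p = 0.0494) or 2.06-fold. VEGFA, an angiogenic growth factor, fell by 1.21 (SE 0.13, adjusted p = 0.0494) or 2.31-fold. The named gene that rose was POLR2L, a small subunit shared by the RNA polymerases, from 6.89 ± 0.13 (SD, n = 3) to 7.88 ± 0.058, a change of 1.0 (SE 0.086, adjusted p = 0.0199) or 1.99-fold. In all, limma called 8 of 22011 probe sets, 2 higher and 6 lower, with changes between 1.88-fold and 2.86-fold. These were the 5 genes named here including CCAR2, 2 probe sets shared by several genes and 1 with no gene symbol. At an unadjusted p under 0.05 the count was 1360, where chance alone gives on average a share of 0.05 of the 22011 probe sets. The same share applies to each such count below, and some of them lie under it. All 3 siDBC1 arrays lay on one side of all 3 siCTR arrays for 8.84% of probe sets, where chance gives at most 10% on average. Leaving out any 1 of the 9 arrays lowered the count to between 0 and 4, with 0 without siCTR replicate 2, siDBC1 replicate 1 or siZNF326 replicate 3 (979, 1048 and 1194 at an unadjusted p under 0.05 in limma). The calls of POLR2L, VEGFA and ASNS were lost in each of the 9 omissions and that of CHAC1 in 5 of them, though the change of CHAC1 stayed between −1.51 and −1.37.

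The integrated stress response list moved as a group. This program raises amino acid synthesis, transport and tRNA charging through ATF4 when translation initiation factor eIF2 is phosphorylated. Of its 34 measured genes, 33 were below siCTR in siDBC1, with a median change of −0.76 (1.69-fold). Of them, 29 were lower when adjusted over the list alone and 3 over all genes (CHAC1, ASNS and VEGFA). Among the members with the smallest p was also DDIT3, which encodes the factor CHOP, at −1.27. The list passed camera (adjusted p = 5.45e-50), with adjusted p = 0.259 with an estimated correlation and 0.0168 by fry. Its median distance from the siCTR mean was −0.69, −1.04 and −0.62 in the 3 siDBC1 arrays and between −0.12 and 0.17 in the siCTR arrays.

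Smaller shifts were seen in 10 other lists in siDBC1. Targets of p53 had a median of 0.27, with 24 of 27 above siCTR and 3 higher when adjusted over the list alone (TP53I3 at 0.87, BAX at 0.84 and CDKN1A at 0.85), none of them over all genes (camera adjusted p = 2.66e-06, adjusted p = 0.746 with an estimated correlation). Heat shock proteins had a median of 0.25, with HSPB1 at 0.47 passing over the list alone (adjusted p = 0.000102, adjusted p = 0.746 with an estimated correlation). Hypoxia targets had a median of −0.12, with VEGFA, DDIT4 and NDRG1 lower over the list alone and VEGFA over all genes (adjusted p = 3.48e-05, adjusted p = 0.835 with an estimated correlation). VEGFA and DDIT4 are members of the stress list too. Replication-dependent histones had a median of −0.13, with 0 of 41 passing over the list alone (adjusted p = 1.65e-05, adjusted p = 0.746 with an estimated correlation). Immediate early genes, the first to respond to growth signals, had a median of 0.10, with JUNB, DUSP6 and IER2 higher and ATF3 lower over the list alone (adjusted p = 0.00255, adjusted p = 0.294 with an estimated correlation). The 5 remaining lists that passed camera had medians between −0.092 and 0.14, and none of them passed with an estimated correlation: core spliceosome genes (0.12, adjusted p = 0.972), NF-kB targets (0.068, adjusted p = 0.259), RNA polymerase II subunits (0.14, adjusted p = 0.875), interferon and double-stranded RNA response genes (0.079, adjusted p = 0.294) and S-phase genes (−0.092, adjusted p = 0.972). Medians depended on the siDBC1 arrays that stood apart. Without siDBC1 replicate 2 they were 0.47 for p53 targets (12 higher and 1 lower over the list alone), 0.40 for heat shock proteins, −0.024 for hypoxia targets, −0.078 for histones, 0.24 for the core spliceosome, 0.32 for RNA polymerase II subunits and 0.11 for S-phase genes. Without siDBC1 replicate 3 they were 0.16, 0.14, −0.24, −0.25, −0.010, −0.070 and −0.25 in the same order. Controls mattered as well: histones were at −0.070 without siCTR replicate 3, and RNA polymerase II subunits and core spliceosome genes at 0.079 and 0.073 without siCTR replicate 1 and at 0.22 and 0.19 without siCTR replicate 3. The call ended without siCTR replicate 3 and without siDBC1 replicate 2 for NF-kB targets (adjusted p = 0.0633 and 0.227), and without siDBC1 replicate 2 for immediate early genes (adjusted p = 0.0779). It also ended for S-phase genes without siCTR replicate 3 (−0.044), siDBC1 replicate 1, siZNF326 replicate 1 or siZNF326 replicate 2, and for interferon response genes without siCTR replicates 2 or 3 or any siDBC1 array (adjusted p from 0.0521 to 0.204). In all 11 of 30 lists passed camera, 7 up and 4 down, 0 with an estimated correlation and 2 by fry (the stress list and NF-kB targets), and 27 of 100 simulated sets of unchanged groups gave as many. Of the 11, 5 passed in each of the 9 omissions of 1 array: stress response, p53, heat shock, hypoxia and histones.

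In the arrays labelled siZNF326 stress response genes were lower as well, and targets of the tumour suppressor p53 were higher, by the medians of their lists. Over all genes 7 of 34 and 2 of 27 members passed, and neither list passed camera with an estimated correlation. CHAC1 went from 7.75 ± 0.17 (SD, n = 3) to 5.56 ± 0.14, a change of −2.19 (adjusted p = 0.00133) or 4.56-fold. Other falls were those of INHBE, an activin subunit, at −1.84 (adjusted p = 0.0216), PCK2, a mitochondrial carboxykinase, at −1.53 (adjusted p = 0.0216), the leucine transporter SLC7A5 at −1.50 (adjusted p = 0.0200), ASNS at −1.24 (adjusted p = 0.0200) and the amino acid transporter SLC43A1 at −1.22 (adjusted p = 0.0216). DDIT3, MARS1, CBS, SLC6A9, GET3 and PHGDH fell by 1.15 to 0.77. The largest rise was that of ZCCHC12, from 5.87 ± 0.23 (SD, n = 3) to 8.17 ± 0.38, a change of 2.29 (SE 0.27, adjusted p = 0.0375) or 4.90-fold. The p53 targets TP53I3 and CDKN1A, the latter an inhibitor of cyclin-dependent kinases, rose by 1.66 (adjusted p = 0.00523) and 1.51 (adjusted p = 0.0216), or 3.15-fold and 2.85-fold. MAP1A, a microtubule-associated protein, rose by 1.47 (adjusted p = 0.0248) and the lysosomal protease CTSA by 1.12 (adjusted p = 0.0216). HSPA2, INPP5D, DUSP6, RHOC, SV2A, GNPDA1 and TMSB10 rose by 0.88 to 1.05. All 3 arrays lay on the named side of all 3 siCTR arrays for each of these 24 genes, which the naming rule required.

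Over all probe sets, limma called 33 in the arrays labelled siZNF326, 20 higher and 13 lower, with changes between 1.51-fold and 4.90-fold. Of these 27 carried 1 gene symbol, 4 several and 2 none. The count at an unadjusted p under 0.05 was 1904, and 18.2% of probe sets were fully separated, where chance gives at most 10% on average. How far single chance groupings exceed that average was not measured, so the 18.2% does not show a change by itself. The balance of directions depended on the scaling: 89 higher and 107 lower after quantile normalization, and 57 higher and 62 lower with arrays centred on their medians. Calls numbered 1 with a replicate block and 5 with only the 2 groups compared in the fit (2007 and 2844 at an unadjusted p under 0.05). The count was 64 without siDBC1 replicate 2, 26 without siDBC1 replicate 3, and 1 to 3 without any other single array. CHAC1 kept its call in 9 of 9 such omissions and TP53I3 in 7, its call being lost without siCTR replicate 3 and without siZNF326 replicate 2 (largest adjusted p = 0.0723), and 23 of the 25 named genes kept theirs in at most 2.

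Of the 34 stress response genes measured, 33 were below siCTR in the arrays labelled siZNF326, with a median of −0.94 (1.91-fold). When adjusted over the list alone 28 were lower, and 7 over all genes. The list passed camera (adjusted p = 1.12e-44), with adjusted p = 0.404 with an estimated correlation and 0.0104 by fry. Its median distance from the siCTR mean was −0.77, −0.96 and −1.05 in the 3 arrays. ATF4 itself, chosen after its values were seen, differed from siCTR by 0.0070 in siDBC1 and by −5.33e-05 in siZNF326. Targets of p53 had a median of 0.73 (1.65-fold), with 26 of 27 above siCTR, 18 higher when adjusted over the list alone and 2 over all genes. The members with the smallest p were TP53I3, CDKN1A, BAX at 0.94 and POLH at 1.23. That list passed camera (adjusted p = 3.6e-13), with adjusted p = 0.556 with an estimated correlation and 0.027 by fry. Its median distance was 1.0 in replicate 1, which stood apart from the other 2 arrays, 0.52 and 0.53. With the array axis as a covariate, chosen after seeing the data, its median was 0.42. Without siZNF326 replicate 1 its median was 0.50 and 8 members passed over the list alone, and 9 passed without siCTR replicate 1 and 9 without siCTR replicate 2.

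**Figure D2:**
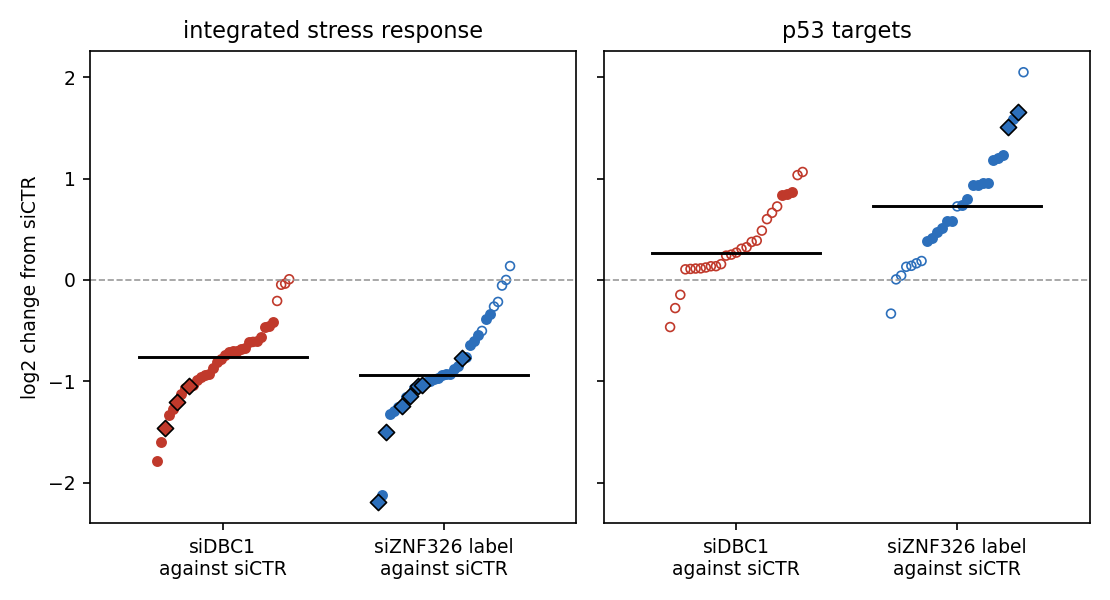
Log2 change from siCTR (y axis) of each measured gene of the integrated stress response and p53 target lists, by comparison (x axis); open points did not pass, filled points passed when adjusted over the list alone, diamonds passed over all genes, and the black line is the median. Stress response medians lie at −0.76 in siDBC1 and −0.94 in the arrays labelled siZNF326, and p53 target medians at 0.27 and 0.73.

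Other lists also passed camera in the arrays labelled siZNF326, and none of them with an estimated correlation. No member named here passed over all genes unless that is stated. Cholesterol synthesis genes had a median of 0.36, with 6 of 19 higher over the list alone, among them FADS2 at 0.67 and HMGCS1 at 0.95 (camera adjusted p = 5.6e-05, adjusted p = 0.786 with an estimated correlation). Genes of oxidative phosphorylation had a median of 0.21, with 4 of 51 higher and 1 lower over the list alone, UQCRQ at 1.0 and NDUFV1 at −0.44 among them (adjusted p = 0.00287, adjusted p = 0.786 with an estimated correlation). Heat shock proteins had a median of 0.28 and 5 of 18 higher over the list alone, with DNAJB1 at 0.66 and HSPA4L at 1.20 (adjusted p = 0.00336, adjusted p = 0.786 with an estimated correlation). Neuronal markers had a median of 0.11 and 3 of 19 higher over the list alone, the neurofilament genes NEFM at 1.72, INA at 0.95 and NEFL at 0.44 (adjusted p = 0.0373, adjusted p = 0.556 with an estimated correlation, 0.0104 by fry). Immediate early genes had a median of 0.10 that turned to −0.019 after quantile normalization, with EGR1, DUSP6 and JUNB higher and MYC lower over the list alone, EGR1 and DUSP6 also over all genes (adjusted p = 0.0160, adjusted p = 0.567 with an estimated correlation). Replication-dependent histones had a median of −0.098 that turned to 0.048 without siCTR replicate 3 (adjusted p = 0.0160, adjusted p = 0.786 with an estimated correlation). Apoptosis genes (0.15, with BAX higher and HRK lower over the list alone), circadian clock genes (0.15) and genes of the siRNA machinery (0.28) passed camera too, each with adjusted p = 0.786 with an estimated correlation, and 4, 5 and 2 of the 9 single-array omissions ended these calls. Those of apoptosis genes ended without siCTR replicates 1 or 2 and without siZNF326 replicates 1 (0.10) or 3, those of circadian clock genes without the same arrays (0.044 without siZNF326 replicate 1) or siDBC1 replicate 2, and those of the siRNA machinery without siCTR replicate 1 (0.16) or siZNF326 replicate 1 (0.18). Other single arrays that moved these lists were siZNF326 replicate 1, without which heat shock proteins were at 0.13 and neuronal markers at 0.055, and siCTR replicate 1, without which oxidative phosphorylation was at 0.14, immediate early genes at 0.064 and histones at −0.17. Neuronal markers no longer passed without siCTR replicate 3, siZNF326 replicate 2 or siZNF326 replicate 3 (adjusted p from 0.0598 to 0.103), nor immediate early genes without siZNF326 replicate 2 (adjusted p = 0.0624). In all 15 of 30 lists passed camera, 13 up and 2 down, 0 with an estimated correlation and 4 by fry, and 14 of 100 simulated sets of unchanged groups gave as many. Of the 15, 6 passed in each of the 9 omissions of 1 array and 10 both after quantile normalization and with arrays centred. With the array axis as a covariate, chosen after seeing the data, 9 passed.

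Lists of the transcription and splicing machinery, which the complex is studied with, had medians of up to 0.34 in the arrays labelled siZNF326 and up to 0.14 in siDBC1. In the arrays labelled siZNF326, RNA polymerase II subunits had a median of 0.34, with POLR2L alone of 10 passing over the list alone (camera adjusted p = 0.00708, adjusted p = 0.786 with an estimated correlation). Elongation factors had a median of 0.31, with HEXIM1 at 0.98 alone of 29 passing over the list alone (adjusted p = 0.00364, adjusted p = 0.786 with an estimated correlation). SR proteins, which bind exonic splicing enhancers, had a median of 0.27 with all 13 above siCTR and 0 passing over the list alone (adjusted p = 0.0160, adjusted p = 0.786 with an estimated correlation). Without siZNF326 replicate 1 elongation factors and SR proteins no longer passed, at 0.18 and 0.19, and core spliceosome genes did not without it (0.063), siCTR replicate 1 (0.080) or siCTR replicate 2. Core spliceosome genes had a median of 0.13 that turned to −0.0043 after quantile normalization (adjusted p = 0.0379, adjusted p = 0.786 with an estimated correlation). With the array axis as a covariate, chosen after seeing the data, 3 of these lists no longer passed camera in siZNF326. They were RNA polymerase II subunits (0.25), SR proteins (0.15) and core spliceosome genes (0.036), while elongation factors passed at 0.13. The hnRNP list did not pass in either group (0.044, adjusted p = 0.292 in siDBC1 and 0.18, adjusted p = 0.128 in siZNF326). In siDBC1 neither elongation factors (0.049, adjusted p = 0.859) nor SR proteins (0.10, adjusted p = 0.910) passed. Partners of SIRT1 and CCAR2 did not pass in siDBC1 (0.12, adjusted p = 0.899) or siZNF326 (0.22, adjusted p = 0.0673), and HDAC3 at 0.72 in siZNF326 passed over the list alone.

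The remaining lists did not pass camera. In siDBC1 these were G2/M genes (−0.058, adjusted p = 0.0561), oxidative phosphorylation (0.057, adjusted p = 0.0791), TGF-beta targets (−0.0059, adjusted p = 0.176), the siRNA machinery (0.12, adjusted p = 0.185), Wnt targets (0.063, adjusted p = 0.454), cholesterol synthesis (0.14, adjusted p = 0.843), ribosomal proteins (0.0078, adjusted p = 0.899), glycolysis (0.0084, adjusted p = 0.899), the unfolded protein response of the endoplasmic reticulum (0.059, adjusted p = 0.899), circadian clock genes (0.025, adjusted p = 0.899) and apoptosis genes (0.039, adjusted p = 0.941). In siZNF326 they were TGF-beta targets (0.11, adjusted p = 0.0662), the unfolded protein response (0.22, adjusted p = 0.129), glycolysis (0.16, adjusted p = 0.244), ribosomal proteins (−0.012, adjusted p = 0.433), Wnt targets (0.075, adjusted p = 0.545), S-phase genes (0.050, adjusted p = 0.642), interferon and double-stranded RNA response genes (0.0081, adjusted p = 0.729), NF-kB targets (0.061, adjusted p = 0.795), hypoxia targets (0.065, adjusted p = 0.924, with VEGFA and DDIT4 lower over the list alone) and G2/M genes (0.10, adjusted p = 0.924). Single members of these lists passed over the list alone and none over all genes. In siDBC1 they were JUNB and TGFB1 among TGF-beta targets, SDF2L1 (0.46) and CALR (0.45) in the unfolded protein response, NDUFB2 (0.62) in oxidative phosphorylation and BAX among apoptosis genes, all higher. In siZNF326 JUNB and TGFB1, CALR (0.58) and PKM (0.31) in glycolysis were higher, and CDT1 (−0.57) among S-phase genes, AURKB (−0.56) among G2/M genes and MYC (−0.63) among Wnt targets were lower. Markers of other cell types were examined for cells other than HEK293. Epithelial (0.042, adjusted p = 0.501), fibroblast (0.0050, adjusted p = 0.949), haematopoietic (0.055, adjusted p = 0.352) and neuronal markers (−0.031, adjusted p = 0.843) did not pass in siDBC1. Epithelial (−0.060, adjusted p = 0.128), fibroblast (0.033, adjusted p = 0.484) and haematopoietic markers (−0.026, adjusted p = 0.173) did not in siZNF326. Neuronal markers did pass camera in siZNF326 (0.11), as given above. A comparison between groups cannot show cells that all arrays share, nor tell other cells from a change within HEK293. The lists therefore do not settle whether other cells were present.

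The siDBC1 and siZNF326 comparisons shared 5 called probe sets, 2 higher and 3 lower, and none was called in opposite directions. The named ones were POLR2L, which rose by 1.0 in siDBC1 and 0.70 in the arrays labelled siZNF326, CHAC1, at −1.46 and −2.19, and ASNS, at −1.04 and −1.24. Independent calls would share 0.0018 higher and 0.0035 lower. Simulated unchanged groups set against 1 shared control group shared 0.05 on average and 5 at most, as many in 1 of 100 sets, so part of the excess may come from the shared controls, which 3 arrays do not allow to be split. Of the 8 probe sets called in siDBC1, 7 had the same direction in siZNF326, and of the 33 called in siZNF326, 32 had it in siDBC1, 29 of them with an unadjusted p under 0.05. Among as many probe sets with the smallest p in simulated unchanged groups with a shared control group, 6.95 of 8 and 28.6 of 33 had the same direction on average. As many came from 78 and 67 of 100 sets. All simulated groups, the control included, were drawn with the same spread along the array axis. The siCTR arrays scored only −16.1 to 4.2 on it, against −54.1 to 46.4 in siDBC1. The simulated shares therefore do not measure what the siCTR arrays themselves add. With an unadjusted p under 0.05 as well, 26 of 100 sets gave as many as 29. Over all probe sets, which are not independent replicates, both sets of changes had a covariance of 0.0399 and a correlation of 0.518, and 64.3% had the same sign. Simulated unchanged groups with a shared control group gave a covariance of 0.0357 (SD 0.0346), a correlation of 0.562 and 71.1% with the same sign. The number of shared calls was 0 or 1 when any 1 array was left out, 46 after quantile normalization, 29 with arrays centred, and 0 with a replicate block or with only the 2 groups compared in the fit (limma counts at an unadjusted p under 0.05 were then 1360 and 1100 in siDBC1 and 2007 and 2844 in siZNF326).

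**Figure D3:**
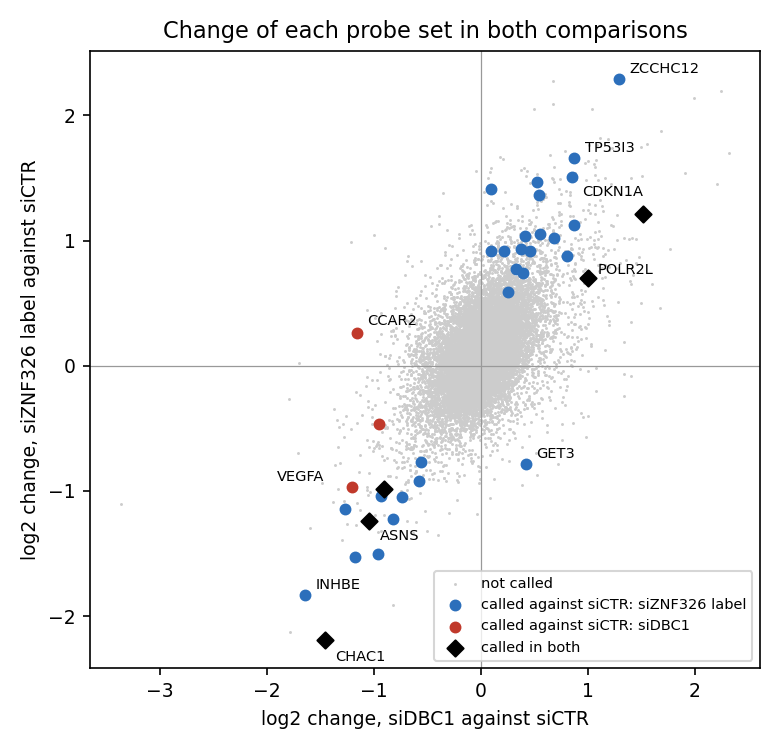
Log2 change from siCTR of each probe set in siDBC1 (x axis) and in the arrays labelled siZNF326 (y axis); black diamonds are the 5 called in both, red points those called in siDBC1 alone and blue points those called in siZNF326 alone. CHAC1 lies at −1.46 and −2.19, and the correlation across probe sets is 0.518.

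Set directly against each other, siDBC1 and the arrays labelled siZNF326 differed in CCAR2 and GET3. CCAR2 was 1.42 higher in the arrays labelled siZNF326 than in siDBC1 (adjusted p = 0.00311) or 2.68-fold, higher in all 3 arrays. GET3, an ATPase that delivers tail-anchored proteins to the endoplasmic reticulum, was lower by −1.21 (SE 0.096, adjusted p = 0.0219) or 2.31-fold. Its arrays read 8.29, 8.37 and 8.45 in siCTR, 8.82, 8.70 and 8.86 in siDBC1 and 7.71, 7.61 and 7.44 in siZNF326. These were the 2 calls of limma, 1 in each direction, against 18 higher and 10 lower after quantile normalization. At an unadjusted p under 0.05 the count was 1609, and 9.45% of probe sets were fully separated (chance at most 10% on average). Leaving out 1 array gave 1 call, or 0 without siZNF326 replicate 3 (1290 at an unadjusted p under 0.05 in limma). The call of GET3 was lost in each of the 9 omissions of 1 array, its change staying between −1.27 and −1.13. That of CCAR2 was lost without siZNF326 replicate 3, at an adjusted p of 0.0511.

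Stress response genes had a median difference of −0.019 (camera adjusted p = 0.0155, adjusted p = 0.928 with an estimated correlation), with 1 of 34 lower over the list alone. The difference was lower under each scaling, at −0.12 after quantile normalization (6 lower over the list alone) and −0.096 with arrays centred. It was −0.14 with the array axis as a covariate (10 lower over the list alone and 2 over all genes). Without the 3 arrays far out on that axis, which left siDBC1 with 1 array, it was −0.22. Both settings were chosen after seeing the data. Single arrays moved it as well, from −0.18 without siDBC1 replicate 2 and −0.11 without siZNF326 replicate 1 to 0.016 without siDBC1 replicate 3. It no longer passed without siDBC1 replicate 3, siDBC1 replicate 1 (−0.0049), siZNF326 replicate 2 (−0.038) or siZNF326 replicate 3. Targets of p53 had a median 0.46 higher in the arrays labelled siZNF326, with 2 higher over the list alone (adjusted p = 2.2e-05, adjusted p = 0.875 with an estimated correlation). That median was 0.26 both without siDBC1 replicate 2 and without siZNF326 replicate 1, and over the list alone 13 members passed without siDBC1 replicate 3 and 1 or 2 without any other array. Cholesterol synthesis (0.32, adjusted p = 0.000175) and hypoxia targets (0.25, adjusted p = 0.000691) were also shifted up, each with adjusted p = 0.928 with an estimated correlation. Neuronal markers had a median difference of 0.14 (adjusted p = 0.0155, adjusted p = 0.228 with an estimated correlation), with INA 1.22 and ENO2 0.61 among them. Elongation factors (0.20), SR proteins (0.22), apoptosis genes (0.14), circadian clock genes (0.13) and the unfolded protein response (0.14, but −0.010 without siDBC1 replicate 2) passed upwards, each with adjusted p = 0.928 with an estimated correlation. NF-kB targets (−0.056), interferon and double-stranded RNA response genes (−0.076), epithelial markers (−0.093) and haematopoietic markers (−0.061) passed downwards, with adjusted p of 0.228, 0.228, 0.38 and 0.34 with an estimated correlation. Most of these calls ended without siDBC1 replicate 2 or siZNF326 replicate 1: elongation factors were then at 0.042 and 0.085, SR proteins at 0.065 and 0.15, apoptosis genes at 0.055 and 0.097, circadian clock genes at 0.059 and 0.071, and epithelial markers at −0.039 and −0.082. Cholesterol synthesis kept its call without them at 0.13 and 0.16, and hypoxia targets without siDBC1 replicate 2 at 0.11. In all 14 of 30 lists passed camera, 9 up and 5 down, 0 with an estimated correlation, and 3 of them (p53 targets, cholesterol synthesis and hypoxia targets) passed in each of the 9 omissions.

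Gene length was compared because the complex is studied in relation to transcript elongation. The 1421 genes with the longest genomic span, 164 kb or more, were set against the others among 14205 genes. Their median change minus that of the others was −0.017 in siDBC1 (camera p = 0.0963, p = 0.731 with an estimated correlation), and it turned to 0.0020 without siDBC1 replicate 2 and passed at −0.067 without siDBC1 replicate 3 (p = 0.0026). In the arrays labelled siZNF326 the difference was 0.026 (camera p = 0.131, p = 0.754 with an estimated correlation), and it passed at 0.057 without siZNF326 replicate 2 (p = 0.0365). Per array it was −0.018, −0.15 and 0.052 in siDBC1 and 0.13, −0.0044 and 0.015 in siZNF326. Between siDBC1 and siZNF326, a length comparison not among those chosen beforehand, long genes differed by 0.069 (camera p = 0.00246, p = 0.536 with an estimated correlation). The p with an estimated correlation was 0.0435 with arrays centred on their medians and 0.0827 after quantile normalization, at differences of 0.069 and 0.070. The difference rested on siDBC1 replicate 2 and siZNF326 replicate 1: it was 0.018 without the former, where it no longer passed, and 0.028 without the latter, against 0.15 without siDBC1 replicate 3 and 0.11 without siZNF326 replicate 2. With the array axis as a covariate it was 0.027. Without the 3 arrays far out on the axis, which left siDBC1 with 1 array, it was 0.018.

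Arrays of one group lay far apart. The first principal component held 45.2% of the variance and placed siDBC1 replicate 2 at 54.0 and siDBC1 replicate 3 and siZNF326 replicate 1 at −43.9 and −53.2, so that siDBC1 replicate 3 lay nearer on it to an array of another group than to those of its own. After the group means were removed, 1 axis held 53% of the remaining variance, with scores of −54.1 for siDBC1 replicate 2, 46.4 for siDBC1 replicate 3, 49.7 for siZNF326 replicate 1 and −16.1 to 4.2 for siCTR. Among random lists matched for size and mean level, G2/M genes, elongation factors and S-phase genes loaded on it at percentiles 100, 99.75 and 99.6, p53 targets at 96.75 and immediate early genes at 0.9. Stress response genes loaded at percentile 20.3. Without these 3 arrays, a choice made after seeing the data, siDBC1 was left with replicate 1 alone, so its values rest on 1 array. The stress response medians were then −0.69 in siDBC1 and −1.02 in siZNF326, and the p53 median in siZNF326 was 0.50.

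**Figure D4:**
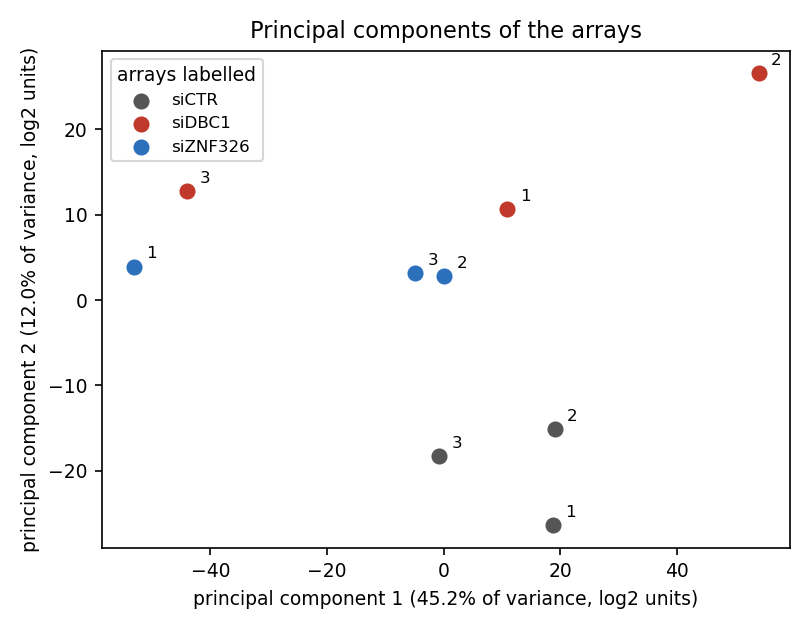
First principal component (x axis, 45.2% of the variance) and second (y axis, 12%) of the log2 values of the 9 arrays, 1 point per array, with its replicate number and the colour of its group. The arrays siDBC1 replicate 3 and siZNF326 replicate 1 lie at −43.9 and −53.2 on the first component and siDBC1 replicate 2 at 54.0.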

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

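The tests of exchanged labels and of a control siRNA that raised the stress genes, the fit with the array axis and the fit without 3 arrays were chosen after the results they address were seen.

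A pair of genes differed between siDBC1 and the arrays labelled siZNF326 by a test of the difference itself. CCAR2 was 1.42 higher on the log2 scale in the arrays labelled siZNF326 than in siDBC1, in all 3 arrays (adjusted p = 0.00311 in limma). GET3 differed by −1.21 (adjusted p = 0.0219), with a change from siCTR of 0.42 in siDBC1 (95% interval 0.20 to 0.64) and of −0.78 in siZNF326. The call of GET3 was lost in each of the 9 omissions of 1 array and that of CCAR2 without siZNF326 replicate 3. With a replicate block or only the 2 groups in the fit, limma made 0 calls here (1769 and 1118 at an unadjusted p under 0.05).

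ZNF326 was not lower in the arrays labelled siZNF326. Arrays exchanged between siDBC1 and siZNF326 are argued against by CCAR2, whose highest siDBC1 array lay 1.02 below the lowest of the other arrays, against a largest SD within a group of 0.096. With the array axis in the model the change was −0.068 (95% interval −0.44 to 0.31), and a fall of 0.5 lay outside that interval. The axis was taken from the residuals of the same arrays, which narrows the interval. Without it the interval ran from −0.63 to 1.20, so whether the axis hid a fall cannot be told. An exchange of the siCTR and siZNF326 labels as a whole cannot be told apart from correct labels, since the difference was 0.28 with an interval from −0.63 to 1.20. Depletion of the protein, a probe set that reads another transcript and recovery of the transcript were not tested, and a change in ZNF326 itself stays open.

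An axis that parts siDBC1 replicate 2 from siDBC1 replicate 3 and siZNF326 replicate 1 held most of the variance within groups. After quantile normalization the first axis, computed anew, held 45.5% of the residual variance. Whether it was the same axis was not tested, so this share does not decide whether unequal distributions left by the authors' normalization are its source. Upper quartiles were 6.70, 7.22 and 7.26 in these 3 arrays in that order, against 6.88 to 7.05 in siCTR. Loadings of the axis in the deposited values followed gene length (Spearman correlation 0.337 across genes) and expression level (0.341 across probe sets). Genes are not independent replicates. A bias of RNA quality or labelling that follows length and level may therefore be part of the axis. A difference in growth state between the cultures may be too, and no test separated these sources, so no biological explanation was tested.

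Integrated stress response genes were lower in siDBC1 and in the arrays labelled siZNF326. List medians as low in both comparisons came from 0 of 100 simulated sets of unchanged groups. The lowest simulated medians were −0.34 in siDBC1 and −0.31 in siZNF326. For this list taken alone, chance variation of the size seen within groups is therefore argued against. The list was singled out by its result among the lists tested, and the simulation made no allowance for that. The sets were drawn from residuals within groups, so a difference particular to the shared siCTR arrays was not measured and stays open. The array axis is argued against as the whole source by size: with it in the model the medians of −0.78 and −1.04 had moved by at most 11.3%, and the list passed camera in both (adjusted p = 0.131 and 0.141 with an estimated correlation). A control siRNA that raised these genes cannot be told apart from a fall shared by both groups, because all 3 siCTR arrays carry the same siRNA. The groups differed by less than either differed from siCTR. Their list medians differed by −0.019, by −0.14 with the axis in the model and by −0.12 after quantile normalization. Without 3 arrays, where siDBC1 was replicate 1 alone, the difference was −0.22. A shared biological effect of both siRNAs stays open as a hypothesis.

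Splits of the 6 arrays of a pair of groups number 10, too few for a share under 0.05. In siDBC1 against siCTR 1 split, the real one, gave 8 calls and the highest other 0; 4 gave as many as the 11 lists found (highest other 16); and 7 gave as large a length difference as 0.017 (highest other 0.10). For siZNF326 against siCTR the numbers were 1 split for 33 calls (highest other 0), 1 for 15 lists (highest other 12) and 6 for a length difference of 0.026 (highest other 0.064). Between siZNF326 and siDBC1 they were 1 split for 2 calls (highest other 0), 3 for 14 lists (highest other 16) and 4 for a length difference of 0.069 (highest other 0.15). The last of these, on length, was not among the tests chosen beforehand. Among 100 splits of all 9 arrays, 1 split, the real one, gave as many as 5 shared calls and the highest other gave 0. A shared call needs calls in both comparisons, which 1 of the other 99 splits had, so these splits do not decide whether chance gives shared calls. A covariance as large as 0.0399 came from 25 of the 100 splits, up to 0.101, so chance cannot be excluded for it.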

How the results depend on the processing

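The array axis as a covariate and the omission of 3 arrays were chosen after seeing the data, and the other alternatives before. Numbers of calls depended strongly on the processing. The change of CCAR2 in siDBC1 kept its direction in each alternative run, as did the stress response and p53 medians against siCTR. CCAR2 stayed between −1.22 and −1.11 and the stress response medians between −0.89 and −0.62 in siDBC1 and between −1.05 and −0.82 in siZNF326, but the p53 medians ran from 0.16 to 0.47 and from 0.42, with the axis as a covariate, to 0.83. The change of ZNF326 in siZNF326 and the difference of long genes in siDBC1 each turned in 1 alternative. Over all alternatives, 1312 values for named genes, lists and comparisons kept their direction and side of the threshold or stayed within 1.5 times, 519 kept their direction and no longer passed, 9 newly passed, 89 moved and 18 turned. Array weights were not run for lists and gene length, because siDBC1 replicate 1 alone got a weight of 75.7. The cause of a change was not tested except where fewer arrays or fewer probe sets are its construction. No background or detection values were used here, so what signal over background limits was not measured, and dim probe sets were examined only through the filters.

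Probe sets called in siDBC1, in siZNF326 and between them, and calls shared by both, were 8, 33, 2 and 5. With quantile normalization they were 69, 196, 28 and 46, with arrays centred 46, 119, 9 and 29, and with the axis as a covariate 454, 462, 179 and 153. With array weights they were 4109, 444, 3625 and 312. There siDBC1 replicate 1 had a weight of 75.7 and the other siDBC1 arrays 0.16 and 0.19. The counts that involve siDBC1 then rest mainly on 1 array of that group. At an adjusted p below 0.01 the first 3 counts were 0, 2 and 1 in limma (1360, 1904 and 1609 at an unadjusted p under 0.05). With the replicate block they were 0, 1 and 0 with 0 shared (1360, 2007 and 1769 at an unadjusted p under 0.05), and the change of CCAR2 in siDBC1 stayed at −1.16 (adjusted p = 0.103). With only the 2 groups compared they were 0, 5 and 0 with 0 shared (1100, 2844 and 1118), and CCAR2 stayed at −1.16 (adjusted p = 0.253). Without the 3 arrays siDBC1 held replicate 1 alone by construction, and the change of CCAR2 on that 1 array was −1.22. Probe sets with 1 symbol gave 52 calls in siZNF326, 4 between siZNF326 and siDBC1 and 10 shared. Probe sets above the median gave 68 in siZNF326 and 8 shared, and those above the lower quartile 8 shared. Trend and robust eBayes gave 4 in siDBC1 and 3 shared.

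Lists passing in siDBC1, in siZNF326 and between them were 11, 15 and 14. The estimated correlation gave 0, 0 and 0, with a smallest adjusted p of 0.228 over the 3 comparisons, and fry gave 2, 4 and 2. Probe sets above the median gave 7, 5 and 7. The axis as a covariate gave 9 between siZNF326 and siDBC1, and the omission of 3 arrays gave 9 in siZNF326 and 6 between them. In siZNF326 the core spliceosome turned to −0.0043 and immediate early genes to −0.019 with quantile normalization. The difference of long genes from the others in siZNF326 newly passed at 0.067 above the lower quartile of level, at 0.062 with a wider set of long genes and at 0.10 among genes of middle level. In siDBC1 it newly passed at −0.042 above the median, at −0.026 among genes of middle level and at −0.050 among those of high level. The axis as a covariate turned SIRT1 in siZNF326 to −0.0017, CCAR1 between siZNF326 and siDBC1 to −0.046 and ZNF326 in siZNF326 to −0.068 (adjusted p = 0.900). Array weights turned SIRT1 in siDBC1 to 0.015, and the omission of 3 arrays turned CCAR1 between siZNF326 and siDBC1 to −0.021. None of these 3 genes passed in the comparison named.

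Without 1 array at a time, calls ranged from 0 to 4 in siDBC1, 1 to 64 in siZNF326 and 0 to 1 between siZNF326 and siDBC1, and shared calls from 0 to 1. The lowest counts at an unadjusted p under 0.05 were 924 in siDBC1 and 976 between siZNF326 and siDBC1 in limma, both under the share of 0.05 that chance gives on average. CCAR2 in siDBC1 ranged from −1.21 to −1.11 and ZNF326 in siZNF326 from 0.13 to 0.42. Lists ranged from 9 to 12 in siDBC1, 9 to 16 in siZNF326 (9 without siZNF326 replicate 1) and 7 to 17 between siZNF326 and siDBC1 (7 without siDBC1 replicate 2 and 7 without siZNF326 replicate 1). Long genes ranged from −0.067 to 0.0020 in siDBC1 and from 0.0057 to 0.057 in siZNF326, and the covariance from 0.0169 to 0.0594. Without siDBC1 replicate 2 the values that turned were CCAR1 between siZNF326 and siDBC1 (−0.066, highest value 0.45 without siDBC1 replicate 3), S-phase genes in siDBC1 (0.11, lowest −0.25), SIRT1 in siDBC1 (0.19, lowest −0.28), the unfolded protein response between siZNF326 and siDBC1 (−0.010, highest 0.31) and long genes in siDBC1 (0.0020). Without siDBC1 replicate 3 they were CCAR1 (−0.070, highest 0.45), RNA polymerase II subunits (−0.070, highest 0.32) and the core spliceosome (−0.010, highest 0.24) in siDBC1, and the stress response between siZNF326 and siDBC1 (0.016, lowest −0.18). Histones in siZNF326 turned without siCTR replicate 3 (0.048, lowest −0.17), and CCAR1 between siZNF326 and siDBC1 without siZNF326 replicate 1 (−0.057). The replicate numbers showed no clear pairing of the arrays. After group means were removed, correlations of arrays with the same number ran from −0.296 to 0.395. Of these 3 of 9 were above 0.1, and 4 arrays correlated best with an array of their own number. So few correlations, on arrays spread along 1 strong axis, do not decide whether the numbers mark shared experiments.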

Other observations

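The genes in this part were chosen after their values were seen, from the fit with the array axis as a covariate, itself chosen after seeing the data. With the axis in the model, limma called 454 probe sets in siDBC1 and 462 in the arrays labelled siZNF326, 153 of them shared in direction. In simulated unchanged groups the same fit called a median of 0, with as many as observed in 0 and 1 of 100 sets. Stress response genes made up part of these calls: 26 members were lower over all genes in siDBC1 and 26 in siZNF326. SLC7A11, the cystine transporter, was at −1.83 (adjusted p = 0.00766) and −2.43 (adjusted p = 0.00352). CTH, which makes cysteine from cystathionine, was at −1.63 in siDBC1 (adjusted p = 0.0122). CEBPG, a bZIP factor that pairs with ATF4, was at −1.49 in siZNF326 (adjusted p = 0.00216), and MTHFD2, a mitochondrial folate enzyme, at −1.40 (adjusted p = 0.0160). Outside that list, ULBP1, a ligand of the natural killer receptor NKG2D, was lower in both, at −1.52 (adjusted p = 0.00766) and −1.16 (adjusted p = 0.00802).

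In that fit 7 of 27 p53 targets were higher over all genes in siDBC1 and 11 in siZNF326, with 10 and 19 higher and 1 lower in each over the list alone. The list medians were 0.23 and 0.42, against 0.27 and 0.73 without the axis. In siDBC1 the apoptosis effector BAX was at 0.83 (adjusted p = 0.0243) and TIGAR, a regulator of glycolysis, at 1.02 (adjusted p = 0.0322), and in siZNF326 the translesion polymerase POLH was at 1.03 (adjusted p = 0.0182). ZCCHC12 was at 1.26 in siDBC1 (adjusted p = 0.0148). The neurofilament gene NEFM was at 1.42 in siZNF326 (adjusted p = 0.0137). LAMP1, a lysosomal membrane protein, was at −0.74 in siDBC1 (adjusted p = 0.0137) and 1.09 higher in siZNF326 than in siDBC1 (adjusted p = 0.00952), and SDCBP, the scaffold protein syntenin, differed between them by −1.11 (adjusted p = 0.00952).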
